A study of Mus musculus with 34 samples.

How the data were processed

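Polyadenylated RNA was measured in 34 libraries of astrocytes isolated magnetically from the cortex of wild-type male mice at 9 ages, from postnatal day 7 (P7) to 18 months (18m). Per the labels' protocols, RNA was extracted on a column kit, cDNA was made with a low-input template-switching kit (SMART-Seq v4), and libraries were sequenced on a NovaSeq. Each age had 3 to 5 libraries. The labels do not say that each library came from a separate animal, so every p-value measures only the spread between these libraries.

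The deposited values are TPM, the share of each gene among all transcripts scaled to a fixed sum, made by the authors, 1 column per library. The submitters' processing notes name Trim Galore 0.6.4, STAR 2.7.1a, RSEM 1.2.28 and DESeq2 1.36.0 with genome build mm10, without saying what each did. Each library summed to 1e+06 TPM over the 20613 genes with values. A further gene had no values in any library. TPM keep no record of read counts, so the depth of each library is unknown and no counting interval or detection limit is given. None of the 13 mitochondrially encoded genes on the lists was in the table, and Xist was not analysed here. A symbol shared by more than 1 gene identifier occurred 28 times, and such genes were kept apart by identifier.

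Values were analysed as log2(TPM + 1), so that fold changes on this scale understate changes in genes of low level. The 14590 genes with at least 1 TPM in at least 3 libraries were tested. A linear model with 1 mean per age was fitted to all 34 libraries with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend and robust settings, statmod 1.5.0). Contrasts were P60 vs P7 for development, 18m vs 3m for aging and each step between neighbouring ages, with an F test over the 9 ages. A separate limma model fitted a slope per month to the libraries from 3m to 18m. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. In the text, "rose" and "fell" refer to called genes. Fold values given with TPM are ratios of the mean TPM of the groups.

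Before the data were examined, 37 gene lists covering astrocyte functions, metabolism, proliferation, immune and stress responses and markers of other brain cell types were fixed, as were the samples, the contrasts, the tests and most alternatives. The 35 lists with at least 5 tested genes were tested with limma's camera, which compares a list with all other genes, with a preset correlation between genes of 0.01. The same test was repeated with an estimated correlation, and fry tested each list on its own. The means of some lists were compared by exact two-sided permutation tests. Of the 42 such tests adjusted together, none passed (smallest adjusted p = 0.107).

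The rule for named genes was also fixed then. For P60 vs P7 and for 18m vs 3m it took the 10 largest rises and the 10 largest falls among called genes with a mean of at least 5 TPM in the higher group, no overlap between groups and a symbol that is not a predicted or clone name. It added the 3 members of smallest p of each list described, the 3 largest rises and falls of each step and of the slope, and a fixed set of astrocyte, myelin and Y-linked genes. Of the 220 genes so named, 219 were found by identifier in GENCODE mouse release 21, from which positions were taken.

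The method was tested on simulated data, normal noise of each gene's own spread around its mean with changes added to a known set of genes. For P60 vs P7, 82.1% of genes changed by a factor of 2 were recovered, with 11 false calls among 170. For 18m vs 3m, 89.6% were recovered, with 15 false calls among 181. The simulated noise was not shared between genes and had the same spread at every age. In the real libraries the median SD of genes in log2 units was 0.13 at P7 and 0.297 at 6m. Genes also deviated together there, as did 9 of 13 neuronal genes. The recovery and false calls therefore describe the simulated data and do not measure performance on the real libraries.

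Alternatives were a pseudocount of 0.1, no filter, a filter of 5 TPM, median-of-ratios rescaling, quantile normalization, array weights, a block for the replicate number, a fold of at least 2, a fit of only the 2 ages compared and leaving out each library in turn. Added after the data were seen were covariates for neuronal and oligodendrocyte transcripts, a term for the number of genes at 0, libraries of 1 range of that number only, 6m in place of 3m, and the slope without 3m. Replicate numbers did not pair libraries across ages: over 119 pairs with the same number, the mean correlation of deviations was 0.0023. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.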

Results

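The series follows gene expression in cortical astrocytes of male mice over development and aging. The 34 libraries covered P7 (n = 4), P14 (n = 4), P21 (n = 3), P28 (n = 3), P60 (n = 3), 3 months (3m, n = 5), 6m (n = 5), 12m (n = 3) and 18m (n = 4). Mature astrocyte markers, 20 genes, had a mean log2(TPM + 1) of 8.79 ± 0.16 (SD, n = 4) at P7 and between 8.96 and 9.41 at the other ages. Slc1a3, which encodes the glutamate transporter GLAST, averaged 2667 ± 249 TPM (SD, n = 4) at P7 and 2386 ± 358 (SD, n = 4) at 18m. Aldoc, an astrocyte-enriched glycolytic enzyme, averaged 4057 ± 443 TPM (SD, n = 4) at P7 and 11920 ± 469 (SD, n = 3) at P60. The Y-linked genes Ddx3y and Eif2s3y were present at both ages, with Ddx3y at 28.5 ± 1.34 TPM (SD, n = 4) at P7 and 33.6 ± 3.11 (SD, n = 3) at P60. Transcripts of other cell types were also present, among them myelin Mbp at 901 ± 133 TPM (SD, n = 3) and neuronal Camk2a at 101 ± 53.7 TPM (SD, n = 3) at P60. The covariates used below cover only neurons and oligodendrocytes, with list means of 4.13 and 4.59 in log2(TPM + 1) at P60. Those of erythroid (8.755), ependymal (7.48), pericyte (6.35) and endothelial genes (5.44) were higher, while microglia (3.36) were lower and fibroblasts (4.25) lay between. Within 6m the endothelial mean ran from 4.17 to 7.05.

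Libraries fell into 3 separate ranges of the number of genes listed at 0. The 14 libraries of P7, P14, 18m and 12m replicates 1 and 2 had 4535 ± 215 genes at 0 (SD). The 9 libraries of P21, P28 and P60 had 3253 ± 245, and the 11 libraries of 3m, 6m and 12m replicate 3 had 1449 ± 181. Chemoreceptor genes, which encode odour, taste and vomeronasal receptors, summed to 42.9 ± 13 TPM (SD, n = 14) in the highest range, 295.8 ± 63 (SD, n = 9) in the middle range and 272.5 ± 87 (SD, n = 11) in the lowest. Only 12m had libraries in 2 ranges. P60 and P7 lie in different ranges with no age between them to link the ranges, so that age and range cannot be told apart in that comparison.

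**Figure D1:**
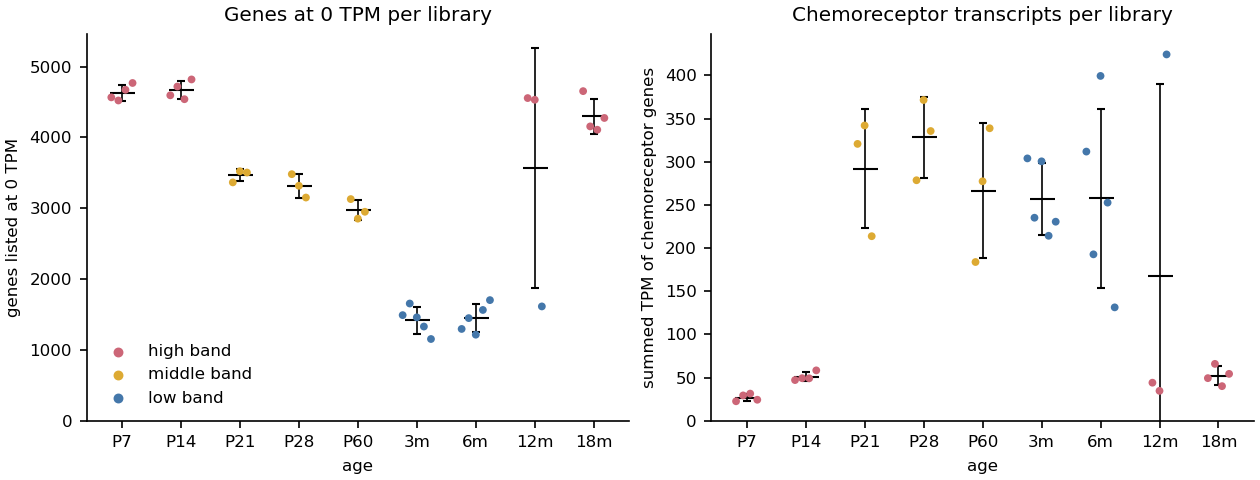
Number of genes listed at 0 TPM in each of the 34 libraries (points), by age; black bars give the mean ± SD. The libraries form 3 ranges with means of 4535, 3253 and 1449 genes, and the 3 libraries at 12m are divided between the highest and the lowest.

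P60 was compared with P7 to describe postnatal development. Proliferation and progenitor genes fell. Aurkb, a mitotic kinase on chromosome 11 (69045647 to 69051664, GRCm38), went from 16.8 ± 2.25 TPM (SD, n = 4) at P7 to 2.97 ± 0.539 (SD, n = 3) at P60, 5.66-fold lower (log2 fold change -2.17 ± 0.17 SE, limma adjusted p = 3.3e-09). Tnc, the matrix protein tenascin C of immature astroglia on chromosome 4 (63959785 to 64047015), was 9.17-fold lower, from 34.5 ± 3.63 TPM (SD, n = 4) to 3.76 ± 0.273 (SD, n = 3). Etnppl, a phosphoethanolamine lyase enriched in astrocytes on chromosome 3 (130617448 to 130637521), was 132-fold higher, from 2.34 ± 2.71 TPM (SD, n = 4) to 307.9 ± 8.1 (SD, n = 3; log2 fold change 7.0 ± 0.89 SE, limma adjusted p = 7.8e-06). Ntsr2, a neurotensin receptor of astrocytes, was 3.01-fold higher, from 828 ± 195 TPM (SD, n = 4) to 2495 ± 70.9 (SD, n = 3).

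All 28 cell cycle genes fell from P7 to P60, and all 28 did so adjusted over the list alone (median log2 fold change -1.5). Ube2c, a mitotic ubiquitin-conjugating enzyme, was 5.06-fold lower and Rrm2, a ribonucleotide reductase subunit, 3.07-fold lower. Camera called the list lower (adjusted p = 1.43e-14), with adjusted p = 0.407 with an estimated correlation. Of 16 progenitor and immature astroglia genes, 12 fell and 1 rose (13 and 1 adjusted over the list alone), among them Igfbp2 at 3.12-fold and the transcription factor Sox4 at 2.44-fold lower (camera adjusted p = 0.00463, adjusted p = 0.407 with an estimated correlation). The largest falls also held Fabp7, a fatty acid binding protein of radial glia (4666 ± 825 TPM, SD, n = 4, at P7 and 735.9 ± 621, SD, n = 3, at P60), Nrep at 6.79-fold and the fibrillar collagen gene Col3a1 at 7.86-fold lower. Scgb3a1, Pla2g3, Slc38a5, Ackr1, Spon2 and Ecscr made up the rest of the 10 largest falls.

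Mature astrocyte markers went both ways: 9 of 20 rose and 4 fell, 7 not being called (10 and 5 adjusted over the list alone). Glul, which encodes glutamine synthetase, was 2.01-fold higher, and Slc1a2, which encodes the glutamate transporter GLT-1, was 1.90-fold higher (210.7 ± 34.1 TPM, SD, n = 4, to 399 ± 32.6, SD, n = 3). Gfap, the astrocyte intermediate filament, was 2.86-fold lower (837 ± 132 TPM, SD, n = 4, to 293 ± 81, SD, n = 3), the water channel Aqp4 was 1.94-fold lower and Aldh1l1 was 1.5-fold lower. Slc1a3 was not called (log2 fold change -0.11 ± 0.14 SE, limma adjusted p = 0.502). Camera called the marker list higher (adjusted p = 0.0204, adjusted p = 0.592 with an estimated correlation), while the exact permutation test of the list mean gave p = 0.0571. Of 23 cholesterol biosynthesis genes, 17 fell and none rose, as did 17 adjusted over the list alone. Fdps was 2.16-fold and Cyp51 2.39-fold lower (camera adjusted p = 0.000149, adjusted p = 0.567 with an estimated correlation). Of 20 genes of glycolysis and glycogen, 13 rose and 2 fell, as they did adjusted over the list alone. Aldoa was 1.67-fold and Ldhb 1.69-fold higher, while Ldha was 2.17-fold lower (camera adjusted p = 0.000109, adjusted p = 0.407 with an estimated correlation).

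Of 32 cytosolic ribosomal protein genes, 23 fell, or 25 adjusted over the list alone, and 6 fell after median-of-ratios rescaling. Rpl6 was 1.60-fold lower (camera adjusted p = 0.00012, adjusted p = 0.592 with an estimated correlation). Of 12 genes of MHC class I antigen presentation, 6 rose and 2 fell, as they did adjusted over the list alone. H2-K1, a class I heavy chain, was 1.92-fold higher and the immunoproteasome gene Psmb9 2.37-fold higher (camera adjusted p = 0.0316, adjusted p = 0.62 with an estimated correlation, exact permutation p = 0.0571 for the list mean). Of 23 interferon-stimulated genes, 4 rose and 1 fell, or 3 and 1 adjusted over the list alone. Ifi27 was 1.90-fold higher (camera adjusted p = 0.0362, adjusted p = 0.743 with an estimated correlation). Of 9 genes of the proteoglycan matrix, 5 fell and 1 rose, as they did adjusted over the list alone. Ncan, which encodes neurocan, was 4.34-fold and Ptprz1 3.24-fold lower (camera adjusted p = 0.0493, adjusted p = 0.592 with an estimated correlation). Thbs4, a synapse-regulating thrombospondin, was 2.48-fold higher.

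Transcripts of other cell types moved with age beside these groups. Of 13 neuronal genes, 9 rose and 1 fell, or 10 and 1 adjusted over the list alone. Camk2a, a kinase of excitatory neurons, was 79.6-fold higher (1.27 ± 0.191 TPM, SD, n = 4, to 101 ± 53.7, SD, n = 3) and the vesicular glutamate transporter Slc17a7 62.1-fold higher (camera adjusted p = 0.000109, adjusted p = 0.407 with an estimated correlation). Nrsn1, Hpcal4, Kif5a, Gng13 and the neurofilament gene Nefl were also among the 10 largest rises, at 38.9-fold to 86.9-fold. Of 13 oligodendrocyte genes, 10 rose and 1 fell, as they did adjusted over the list alone. Myelin Mbp was 53.9-fold higher, and Mobp was listed at 0 in all 4 libraries at P7 and averaged 172 ± 14.3 TPM (SD, n = 3) at P60 (camera adjusted p = 0.000479, adjusted p = 0.567 with an estimated correlation). Of 15 microglial genes 8 rose, 8 also adjusted over the list alone, with P2ry12 3.47-fold higher (camera adjusted p = 0.000597, adjusted p = 0.567 with an estimated correlation). Of 8 immature neuron genes 4 rose, 4 also adjusted over the list alone, with Neurod2 10.3-fold higher (camera adjusted p = 0.00593, adjusted p = 0.407 with an estimated correlation). Of 7 fibroblast genes 6 fell, 6 also adjusted over the list alone, with Col1a2 3.30-fold lower (camera adjusted p = 0.00484, adjusted p = 0.567 with an estimated correlation).

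In total 7697 of 14590 genes were called between P60 and P7 (limma), 2839 higher and 4858 lower at P60, and the median over all genes was -0.15. After median-of-ratios rescaling 7247 were called, 4122 higher and 3125 lower, with a median of 0.01. Of the 7697, 5964 were called in both settings in the same direction. Of the 35 lists, camera called 16, and none with an estimated correlation. With covariates for neuronal and oligodendrocyte transcripts, added after the data were seen, 3700 genes were called, and of 60 named and called genes 38 were still called, among them Aurkb (log2 fold change -1.87, adjusted p = 3.14e-06). Of the 22 others 6 kept at least 0.5 of their fold. Camk2a, Slc17a7, Nefl, Rbfox3, Mbp and Mobp belong to the lists whose means were the covariates, so that their loss of change is largely fixed by the adjustment. The neuronal or myelin genes Nrsn1, Mbp, Hpcal4, Kif5a, Gng13 and Nefl turned direction, uncalled (Mbp from 5.66 to -1.53 and Kif5a from 5.45 to -1.13), and Camk2a, Mobp, Slc17a7, Rbfox3, Neurod2 and P2ry12 were not called, nor was Amigo2, whose fold held while its error grew (0.66 ± 0.18 SE to 0.64 ± 0.26 SE, adjusted p = 0.0703). Of the largest falls Slc38a5 (-3.11 to -1.01, adjusted p = 0.303), Ecscr (-2.68 to -0.79, 0.278), Scgb3a1 (-3.37 to -1.69, 0.232), Fabp7 (-2.96 to -1.61, 0.257) and Ackr1 (-3.08 to -2.46, 0.158) were not called. Several astrocyte genes also moved closer to 0 and lost their call. Gfap went from -1.54 ± 0.35 (SE) to -0.72 ± 0.38 (adjusted p = 0.161), Slc1a2 from 0.93 ± 0.23 to 0.31 ± 0.28 (0.429), Glul from 1.01 ± 0.19 to 0.35 ± 0.20 (0.215) and Aldoc from 1.56 ± 0.29 to 0.86 ± 0.36 (0.079), and camera no longer called the mature marker list (adjusted p = 0.57). Without P60 replicate 2 the P60 vs P7 calls of the MHC class I, interferon-stimulated and proteoglycan lists were lost (camera adjusted p = 0.102, 0.148 and 0.0713), as were the interferon-stimulated and proteoglycan calls without P7 replicate 3 (0.0771 and 0.0758) and the proteoglycan call without P60 replicate 1 (0.0553).

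**Figure D2:**
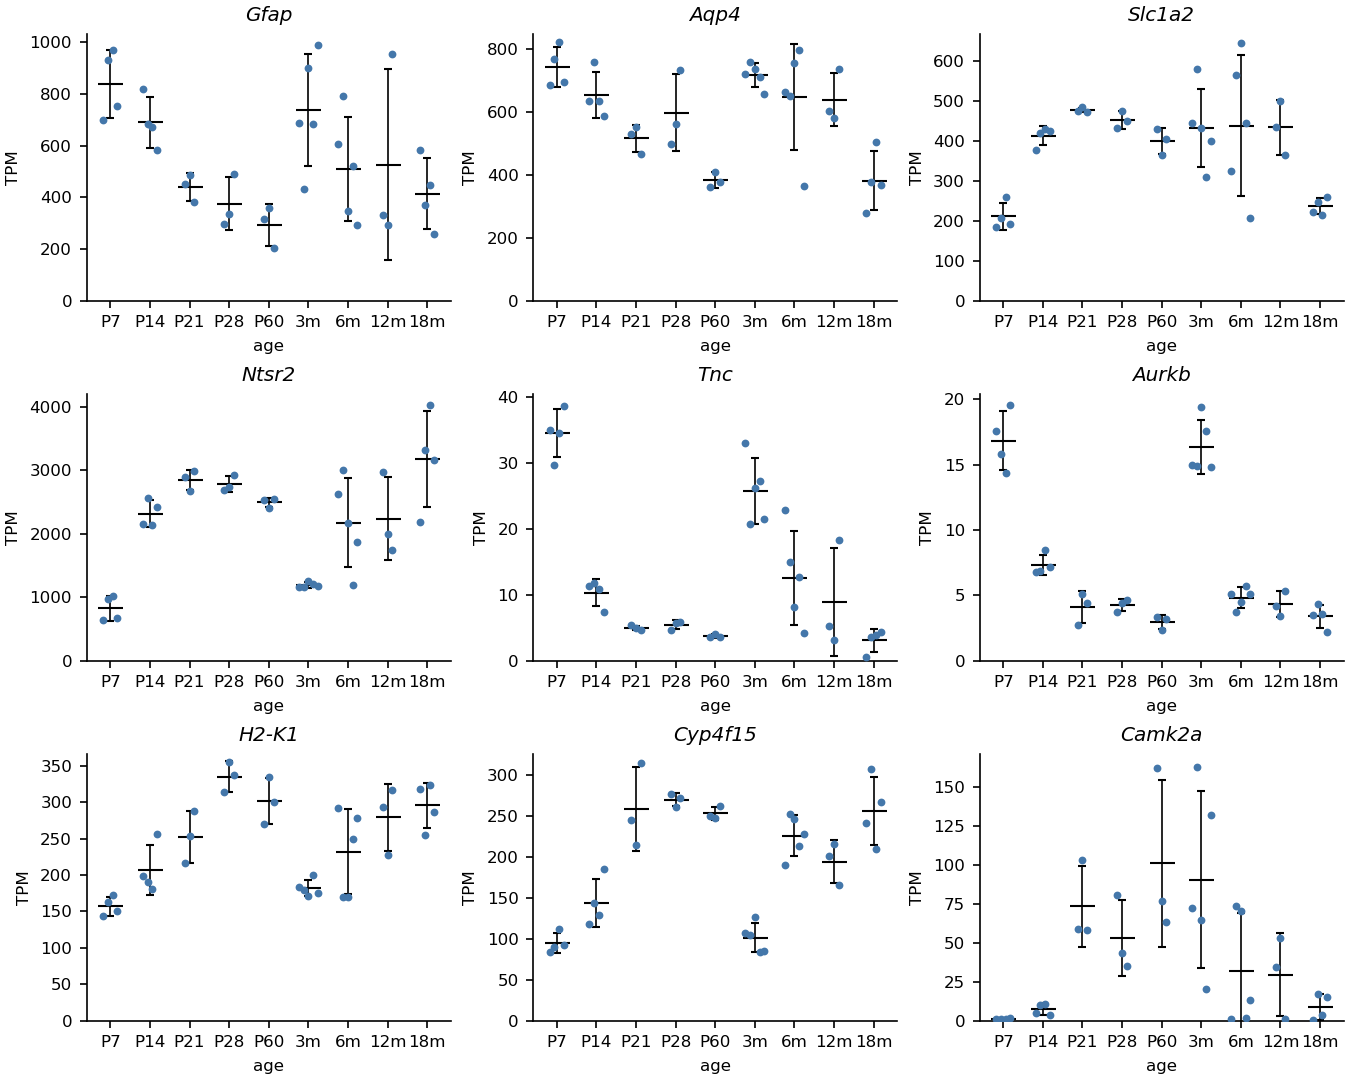
TPM of Gfap, Aqp4, Slc1a2, Ntsr2, Tnc, Aurkb, H2-K1, Cyp4f15 and Camk2a by age, with 1 point per library and black bars for the mean ± SD. Aurkb averaged 16.8 TPM at P7, 2.97 at P60, 16.3 at 3m and 3.39 at 18m.

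The comparison of 18m with 3m addresses aging. Proliferation genes were lower at 18m than at 3m. The cell cycle list mean was 2.37 at P60, 3.71 at 3m, 2.82 at 6m and 2.40 at 18m (exact permutation p = 0.00794 for 18m vs 3m). The level at 18m was thus near that of the young adult P60, and 3m stood above both. Aurkb went from 16.3 ± 2.07 TPM (SD, n = 5) at 3m to 3.39 ± 0.904 (SD, n = 4) at 18m, 4.81-fold lower (log2 fold change -2.00 ± 0.15 SE, limma adjusted p = 9.79e-10), and Tnc was 8.26-fold lower, from 25.8 ± 5 TPM (SD, n = 5) to 3.12 ± 1.74 (SD, n = 4). Thbs4 was 5.55-fold lower, from 41.2 ± 7.05 TPM (SD, n = 5) to 7.43 ± 1.19 (SD, n = 4; log2 fold change -2.32 ± 0.20 SE, limma adjusted p = 7.45e-09). Higher at 18m were Cyp4f15, a cytochrome P450 that hydroxylates fatty acids and eicosanoids on chromosome 17 (32685627 to 32703352), at 2.53-fold (101.5 ± 17.5 TPM, SD, n = 5, to 256.6 ± 41.3, SD, n = 4; limma adjusted p = 1.09e-07), and Ntsr2 at 2.65-fold (1196 ± 41.8 TPM, SD, n = 5, to 3176 ± 761, SD, n = 4). H2-K1 was 1.62-fold higher, from 182 ± 11.1 TPM (SD, n = 5) to 295.5 ± 31.3 (SD, n = 4).

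Of 28 cell cycle genes, 25 fell and 3 were not called, or 27 fell adjusted over the list alone. Rrm2 was 3.35-fold lower and Top2a, a topoisomerase of dividing cells, 4.55-fold lower (camera adjusted p = 2.53e-15, adjusted p = 0.405 with an estimated correlation). Of 16 progenitor and immature astroglia genes 7 fell and none rose, 7 also adjusted over the list alone, and 7 fell and 1 rose after rescaling. Camera did not call that list (adjusted p = 0.357, 0.888 with an estimated correlation), while fry called it lower (adjusted p = 0.00019). Of 12 MHC class I genes 4 rose and none fell, 4 also adjusted over the list alone, with Psmb8 1.79-fold higher (camera adjusted p = 6.18e-07, adjusted p = 0.405 with an estimated correlation, 0.0315 with the neuronal and oligodendrocyte covariates). With those covariates H2-K1 went from a log2 fold change of 0.69 ± 0.14 (SE) to 0.26 ± 0.15 (adjusted p = 0.18) and Psmb8 from 0.80 ± 0.18 to 0.33 ± 0.22 (0.236), and neither was called. The MHC class I list mean was 5.84 at P60, 5.49 at 3m, 5.56 at 6m and 5.89 at 18m (exact permutation p = 0.00794 for 18m vs 3m and 0.254 for 18m vs 6m). At 18m it was thus near that at P60. Of 11 genes of neuroinflammatory reactive astrocytes 4 rose, 4 also adjusted over the list alone. Amigo2 was 2.02-fold and the matrix gene Fbln5 2.21-fold higher (camera adjusted p = 9.24e-05, adjusted p = 0.405 with an estimated correlation). Of 23 interferon-stimulated genes 2 rose, or 1 adjusted over the list alone, with Ifi27 1.56-fold higher (camera adjusted p = 0.000111, adjusted p = 0.622 with an estimated correlation). With the covariates neither Ifi27 (log2 fold change 0.28, adjusted p = 0.291) nor the list (camera adjusted p = 0.486) was called. Of 13 pan-reactive genes none rose and 2 fell, or 1 adjusted over the list alone. The 2 were the hyaluronan receptor Cd44 at 2.16-fold and Gfap at 1.78-fold lower, yet the list median was 0.16 and camera called the list higher (adjusted p = 0.0299, adjusted p = 0.622 with an estimated correlation). Gfap was not called after median-of-ratios rescaling (log2 fold change -0.59), nor without 18m replicate 2 (adjusted p = 0.0675), 18m replicate 4 (0.124), 3m replicate 3 (0.0703) or 3m replicate 5 (0.0801). Nor was it called with the covariates (-0.66 ± 0.34 SE, adjusted p = 0.136), and with a term for the number of genes at 0 its direction turned (0.77 ± 0.55 SE, adjusted p = 0.527). The pan-reactive call in 18m vs 3m was lost without 3m replicate 2 (camera adjusted p = 0.0662) or 18m replicate 1 (0.33).

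Of 12 complement genes 2 rose, or 1 adjusted over the list alone, with C3 5.23-fold higher, from 0.631 ± 0.283 TPM (SD, n = 5) to 3.30 ± 1.49 (SD, n = 4). The list median was -0.08 and the mean -0.13, while camera called it higher (adjusted p = 0.0482, adjusted p = 0.425 with an estimated correlation). The call in 18m vs 3m was lost without 3m replicates 1, 2 or 4 (adjusted p = 0.0606, 0.0919 and 0.0966) or 18m replicates 1, 2 or 3 (0.16, 0.0555 and 0.0513). Of 10 senescence-associated genes only Igfbp5 was called, 2.52-fold lower, and 1 fell adjusted over the list alone, with a list median of 0.32 (camera higher, adjusted p = 0.012, adjusted p = 0.425 with an estimated correlation). Of 20 genes of glycolysis and glycogen, 6 rose and 4 fell, or 7 and 4 adjusted over the list alone, with Gapdh 1.31-fold higher, which was not called after quantile normalization (camera adjusted p = 0.00164, adjusted p = 0.425 with an estimated correlation). Of 32 ribosomal protein genes 3 rose and 1 fell, or 1 and none adjusted over the list alone. Their median was -0.03, and 0.23 after rescaling, and camera called them higher (adjusted p = 0.0023, adjusted p = 0.869 with an estimated correlation). The ribosomal list mean was 8.12 at 3m and 8.10 at 18m (exact permutation p = 0.817). The ribosomal and senescence calls were lost without 18m replicate 1 (adjusted p = 0.232 and 0.0769) and the glycolysis call without 18m replicate 2 (0.0555).

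Mature astrocyte markers were not called as a list (camera adjusted p = 0.842), though 9 of 20 fell and 3 rose, or 9 and 4 adjusted over the list alone. After rescaling 5 fell and 5 rose. Aqp4 was 1.88-fold lower (716 ± 37.8 TPM, SD, n = 5, to 382 ± 93.2, SD, n = 4) and Slc1a2 1.83-fold lower (432 ± 97.9 TPM, SD, n = 5, to 235.7 ± 20.1, SD, n = 4), and Aldh1l1 was not called (limma adjusted p = 0.122). With the covariates Slc1a2 went from a log2 fold change of -0.85 ± 0.20 (SE) to -0.43 ± 0.25 (adjusted p = 0.187) and was not called. The largest rises also held Inmt, an indolethylamine methyltransferase, at 7.11-fold (5.96 ± 4.92 TPM, SD, n = 5, to 42.4 ± 15.4, SD, n = 4), Cyp2d22 at 2.63-fold, the MHC class II gene H2-Aa at 3.27-fold, Dmp1, Mroh7, Ctsw, Wfdc17 and Htra3. With the covariates Inmt (2.87 to 0.54, adjusted p = 0.639) and H2-Aa (1.42 to 0.77, adjusted p = 0.109) were not called, and with the term for genes at 0, which enlarged the errors, none of these 8 was. Under that term Inmt (3.92), H2-Aa (2.16) and Htra3 (1.26 to 1.85) had larger folds, Cyp2d22 a similar one (1.46 ± 0.20 SE to 1.38 ± 0.46 SE), and Dmp1 turned from 1.7 to -0.14.

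Neuronal genes were lower at 18m: 9 of 13 fell, 9 also adjusted over the list alone. Camk2a was 10-fold lower (90.7 ± 56.7 TPM, SD, n = 5, to 9.07 ± 8.43, SD, n = 4) and Rbfox3, which encodes the neuronal nuclear antigen NeuN, 7.01-fold lower (camera adjusted p = 0.0408, adjusted p = 0.78 with an estimated correlation). The list call in 18m vs 3m was lost without 3m replicates 2 or 5 (adjusted p = 0.0525 and 0.161) or 18m replicates 1, 3 or 4 (0.0559, 0.0906 and 0.0888). Rims1 and Rasgef1a were 10.7-fold and 11.9-fold lower, and Zfp365 7.13-fold. Nrsn1, Hpcal4, Kif5a, Gng13 and Psd were also among the largest falls, but without 18m replicate 1 their adjusted p was 0.105, 0.0837, 0.137, 0.104 and 0.0565, and for Kif5a it was 0.0544 without 3m replicate 2. Their log2 fold changes of -3.79, -3.76, -3.69, -3.27 and -3.02 shrank to -2.76, -2.76, -2.57, -2.44 and -2.28 without 18m replicate 1. Of 8 immature neuron genes 6 fell, 6 also adjusted over the list alone, with Neurod2 8.22-fold lower (camera adjusted p = 0.0157, adjusted p = 0.425 with an estimated correlation). That list was not called by camera with 6m in place of 3m either (adjusted p = 0.953). Of 10 genes of oligodendrocyte precursors 5 rose, or 6 adjusted over the list alone. Neu4 was 3.54-fold and the transcription factor Olig1 1.88-fold higher (camera adjusted p = 5.62e-07, adjusted p = 0.405 with an estimated correlation). The precursor list mean was 3.87 at 3m and 4.81 at 18m (exact permutation p = 0.103).

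No oligodendrocyte, pericyte or erythroid gene was called by limma over all genes or adjusted over the list alone, while camera called the 3 lists higher. Their adjusted p-values were 0.00205, 0.00391 and 0.00164, and adjusted p = 0.622, 0.569 and 0.425 with an estimated correlation. The oligodendrocyte list mean was 3.44 at 3m and 3.57 at 18m (exact permutation p = 0.873). Mbp averaged 661 ± 557 TPM (SD, n = 5) at 3m and 243 ± 242 (SD, n = 4) at 18m (limma adjusted p = 0.226), the pericyte gene Vtn 1917 ± 200 TPM (SD, n = 5) and 3052 ± 921 (SD, n = 4), and haemoglobin Hba-a1 1490 ± 347 TPM (SD, n = 5) and 4417 ± 2700 (SD, n = 4).

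In total 5476 of 14590 genes were called between 18m and 3m (limma), 607 higher and 4869 lower at 18m, with a median over all genes of -0.24. After median-of-ratios rescaling 5334 were called, 2564 higher and 2770 lower, with a median of -0.02. Of the 5476, 3377 were called in both settings in the same direction. Such rescaling centres the middle gene, and among calls with a fold of at least 2 the larger share was lower as deposited (57 higher, 686 lower) and after it (125 higher, 460 lower). With the covariates 3899 were called, 155 higher and 3744 lower, and of 50 named and called genes 29 were still called. Beside Gfap, Slc1a2, H2-K1, Psmb8, Ifi27, Inmt and H2-Aa, those that were not were Slc1a3 (-0.34 ± 0.12 SE to -0.34 ± 0.17 SE), Arntl (-0.83 to -0.62) and Neu4 (2.06 to 1.48), which kept most of their fold, Psmb9 (0.76 to 0.19) and the 10 genes Camk2a, Nrsn1, Hpcal4, Kif5a, Gng13, Psd, Rims1, Rasgef1a, Zfp365 and Neurod2. Quantile normalization gave 2107 higher and 1823 lower of 3930. Without 18m replicate 1, 3471 were called. Slc1a3 was not called in 4 of the 9 fits without 1 library (highest limma adjusted p = 0.188, without 18m replicate 1). Psmb9 lost its call in 1 of them (0.0543, without 18m replicate 1). With a term for the number of genes at 0, which rests on the 3 libraries of 12m and was added after the data were seen, 39 were called by limma, and 2335 had an unadjusted p under 0.05. Of the 50 named and called genes 2 were still called, Aurkb (-1.59 ± 0.30 SE, adjusted p = 0.0293) and Thbs4 (-2.29 ± 0.42 SE, adjusted p = 0.0276), while Tnc went from -2.83 ± 0.37 SE to -0.93 ± 0.73 SE (adjusted p = 0.57). Of the 48 others 40 kept at least 0.5 of their fold and 26 had one at least as large, such as Camk2a (-3.53 to -7.94), C3 (1.34 to 2.12) and H2-K1 (0.69 to 0.99), and their SE was larger by a median factor of 2.2. The term rests on 12m replicate 3 against the other 12m libraries, and it had the lowest neuronal list mean at 12m (2.61, highest 4.24). The term therefore also carries that low neuronal level, so larger neuronal folds under it do not show that those changes held. Of the 35 lists camera called 15, 12 higher and 3 lower relative to all other genes, 9 after rescaling and none with an estimated correlation. Fry, which tests a list on its own, also called 15 but 2 higher, MHC class I and oligodendrocyte precursors, and 13 lower, and the complement and ribosomal lists that camera called higher had medians of -0.08 and -0.03.

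**Figure D3:**
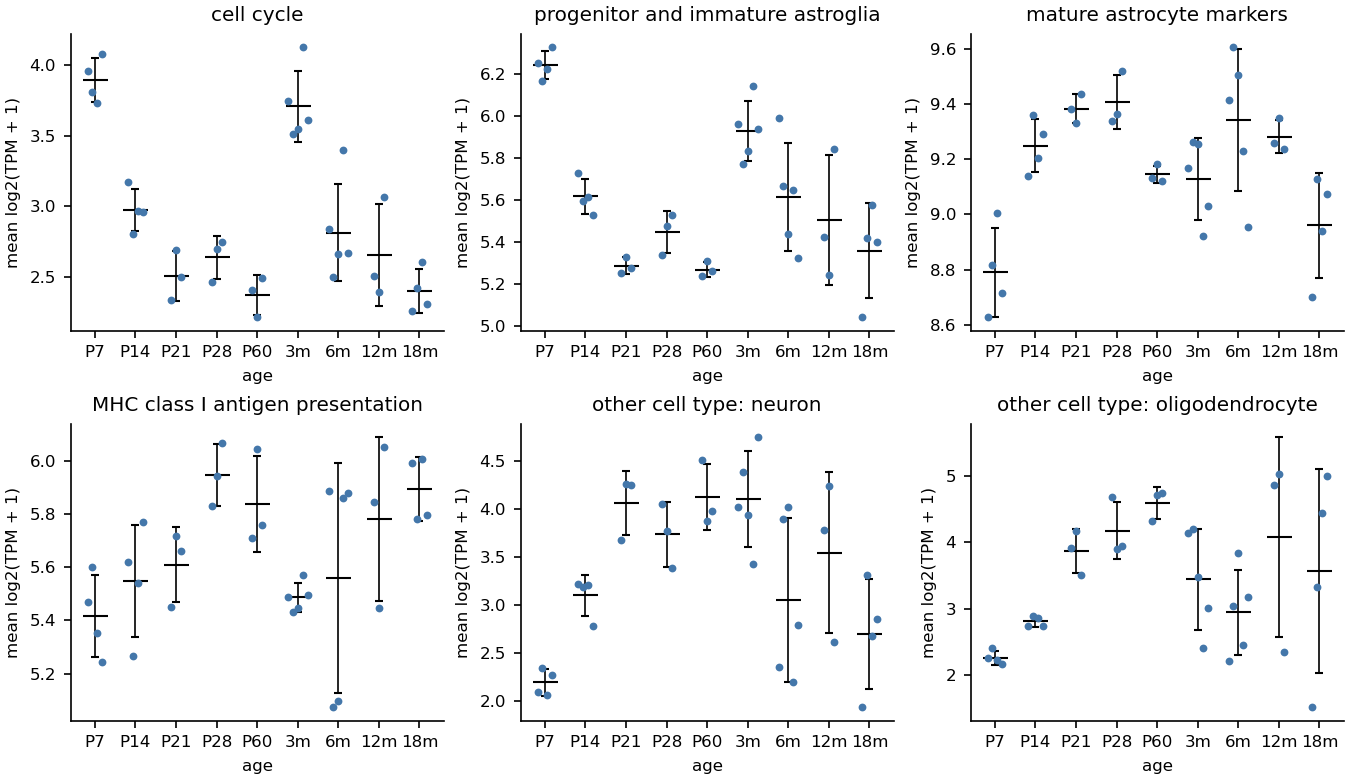
Mean log2(TPM + 1) of 6 gene lists (cell cycle, progenitor and immature astroglia, mature astrocyte markers, MHC class I, neuron, oligodendrocyte) by age, with 1 point per library and black bars for the mean ± SD. The cell cycle mean was 3.89 at P7, 2.37 at P60, 3.71 at 3m and 2.40 at 18m.

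The calls of development and aging were compared to ask whether aging repeats or opposes the developmental change. Tnc and Aurkb fell in both, Ntsr2 and H2-K1 rose in both, and Camk2a and Thbs4 rose in development and fell in aging. The same direction in both does not mean a continued change. Tnc and Aurkb were higher at 3m than at P60 and Ntsr2 was lower. The MHC class I list mean was 5.84 at P60, 5.49 at 3m and 5.89 at 18m. In all 3277 genes were called in both. Of these, 1497 fell in both, 215 rose in both, 1263 rose and then fell and 302 fell and then rose, so that 47.8% went opposite ways. The odds ratio for direction was 0.844 (Fisher's exact test, two-sided p = 0.0831). After rescaling 57.8% of 3293 genes went opposite ways (odds ratio 0.575, Fisher's exact p = 1.06e-14). Genes are not independent replicates, so the p-values of these Fisher's tests do not measure a spread between libraries. Both comparisons also cross the ranges of genes at 0. P60 vs P7 goes from the highest to the middle range and 18m vs 3m from the lowest to the highest. A difference between ranges could therefore give opposite directions, and cannot be told apart from age here. Across genes, which are not independent replicates, the fold changes correlated with r = -0.20. Without 3m replicate 2 the odds ratio was 1.05. Fisher's exact test passed its threshold without any 1 of P7 replicates 2 and 3, P60 replicate 3, 3m replicate 4 and 18m replicates 2 and 4, with odds ratios of 0.776, 0.757, 0.741, 0.661, 0.771 and 0.723.

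The steps between neighbouring ages place the calls in time. P14 to P21 crosses from the highest to the middle range of genes at 0 and P60 to 3m from the middle to the lowest, with no age that links the ranges, so that age and range cannot be told apart in these steps either, and 6m to 12m and 12m to 18m are divided between ranges by the libraries of 12m. From P7 to P14, Etnppl rose 20.4-fold (2.34 ± 2.71 TPM, SD, n = 4, to 47.6 ± 26.8, SD, n = 4; limma adjusted p = 0.00361), the neuropeptide gene Vip rose from 0.013 ± 0.026 TPM (SD, n = 4) to 9.11 ± 2.93 (SD, n = 4) and Kirrel2 rose 8.88-fold. The urea transporter gene Slc14a2 fell 4.44-fold, the cholesterol 25-hydroxylase gene Ch25h 5.39-fold and the potassium channel subunit gene Kcnmb4 4.05-fold. Of 28 cell cycle genes 26 fell, or 28 adjusted over the list alone (camera adjusted p = 9.28e-18, adjusted p = 0.222 with an estimated correlation). Limma called 1728 genes, 478 higher and 1250 lower, and after rescaling 1068 higher and 609 lower. The count was 744, 899, 1020 and 628 without P7 replicates 1 to 4 in turn, and 732, 935 and 722 without P14 replicates 2, 3 and 4.

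From P14 to P21, activity-regulated Arc rose 14-fold (2.15 ± 0.937 TPM, SD, n = 4, to 30.0 ± 19.1, SD, n = 3), and the presynaptic gene Rims1 and Zfp365 rose 10.5-fold and 9.35-fold. Snorc fell 4.08-fold and the leukotriene receptor gene Cysltr2 4.19-fold. Without P21 replicate 2, none of these 5 was called (adjusted p = 0.101, 0.125, 0.118, 0.101 and 0.0773 for Arc, Rims1, Zfp365, Snorc and Cysltr2), and Rims1, Zfp365 and Snorc were each lost in at least 3 further fits. With the covariates Arc went from a log2 fold change of 3.17 to 1.46 (adjusted p = 0.0376), Rims1 from 3.09 to 0.96 (0.076) and Zfp365 from 3.02 to 0.94 (0.0176), and Rims1, Cysltr2 (-1.68 to -1.1, 0.0867) and Snorc, whose fold nearly held (-1.5 to -1.39, 0.0929), were not called. The neuronal list mean was 3.10 ± 0.21 (SD, n = 4) at P14 and 4.07 ± 0.33 (SD, n = 3) at P21. Limma called 1925 genes, 817 higher and 1108 lower, and after rescaling 1295 higher and 760 lower. The count was 566 without P21 replicate 2, 1204 and 1096 without P21 replicates 1 and 3, and 1052 and 1200 without P14 replicates 3 and 4.

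From P21 to P28 limma called 3 genes, all higher, with 1007 at an unadjusted p under 0.05. They were Plac9b (4.01-fold), Plac9a (4.07-fold) and Tmem254c (1.87-fold). Plac9a and Plac9b are close copies of each other, as are Tmem254a, Tmem254b and Tmem254c, all on chromosome 14, so the copy behind the reads is uncertain. Limma called no gene without P28 replicate 2 or without P28 replicate 3 (799 and 569 at an unadjusted p under 0.05), and 1 without P21 replicate 3. From P28 to P60, Tmem254b fell 4.45-fold (82.0 ± 2.47 TPM, SD, n = 3, to 18.4 ± 2.05, SD, n = 3; limma adjusted p = 3.08e-06) and Tmem254a 5.11-fold, and Ccl21b, of a repeated chemokine family, went from 22.1 ± 2.6 TPM (SD, n = 3) to being listed at 0. Wdfy1 rose 2.93-fold, Crip1 1.95-fold and the sterol hydroxylase gene Cyp27a1 1.96-fold. Limma called 163 genes, 31 higher and 132 lower, and after rescaling 55 higher and 73 lower. The count was 12 and 9 without P28 replicates 2 and 3, and 30, 13 and 42 without P60 replicates 1 to 3, and of the 6 named genes only Tmem254b was called in every fit without 1 library.

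From P60 to 3m, genes of cell division rose. Nrep rose 7.28-fold (14.9 ± 0.252 TPM, SD, n = 3, to 108.8 ± 10.2, SD, n = 5; limma adjusted p = 2.29e-07), Tnc 6.85-fold and Col3a1 7.38-fold. Etnppl fell 20.1-fold, Inmt 9.69-fold, and Exosc6, an RNA exosome subunit gene at 7.63 ± 0.358 TPM (SD, n = 3) at P60, was listed at 0 in all 5 libraries at 3m. It was at 0 in all 17 libraries from 3m to 18m and at 3.86 TPM or more in all 17 younger ones, and no other gene was at 0 in one of these sets and at 1 TPM or more throughout the other. The split falls exactly between the ages labelled in days and those labelled in months, and its source was not tested. Of 28 cell cycle genes 26 rose, 26 also adjusted over the list alone (camera adjusted p = 6.33e-31, adjusted p = 0.0836 with an estimated correlation). Among 7 lists of other cell types that can divide, camera called fibroblasts higher at 3m (median log2 fold change 0.945, adjusted p = 0.000992). It called oligodendrocyte precursors and pericytes lower (adjusted p = 0.0254 and 0.0453). Of 16 progenitor and immature astroglia genes, Tnc among them, 6 rose and none fell, or 7 rose adjusted over the list alone (camera adjusted p = 0.00384, adjusted p = 0.424 with an estimated correlation). Limma called 1487 genes, 1205 higher and 282 lower, and after rescaling 660 higher and 689 lower. The count was 773, 717 and 675 without P60 replicates 1 to 3.

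From 3m to 6m, Cyp4f15 rose 2.23-fold (101.5 ± 17.5 TPM, SD, n = 5, to 226 ± 25.1, SD, n = 5; limma adjusted p = 2.44e-06), Cyp2d22 2.47-fold and Cables1 2.13-fold. The serotonin receptor gene Htr5b fell 5.73-fold, Plac9b 3.16-fold and Ccdc78 4.95-fold. Of 28 cell cycle genes 23 fell, or 26 adjusted over the list alone (camera adjusted p = 4.65e-22, adjusted p = 0.151 with an estimated correlation). Among the 7 lists of other cell types that can divide, camera called only immature neurons, lower at 6m (adjusted p = 0.000171). Their list mean was 2.29 at 3m and 1.61 at 6m. Limma called 1360 genes, 302 higher and 1058 lower, and after rescaling 888 higher and 1020 lower. The count was 877 and 574 without 3m replicates 4 and 5 and 699 without 6m replicate 1, and a fit of these ages alone called 7.

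From 6m to 12m limma called 8 genes, 5 higher and 3 lower. The Polycomb gene Cbx7 rose 2.47-fold (11.4 ± 2.71 TPM, SD, n = 5, to 28.3 ± 5.32, SD, n = 3; limma adjusted p = 0.000918) and was called in every fit without 1 library, but not with the term for genes at 0 (1.18 ± 0.29 SE, adjusted p = 0.152). The matrix gene Agrn and the muscle-type adenylosuccinate synthase gene Adssl1 rose 2.21-fold and 2.48-fold, and Fkbp11 and the epoxide hydrolase gene Ephx2 fell 2.24-fold and 1.77-fold. Without 12m replicate 1 these 4 were not called (adjusted p = 0.25, 0.0926, 0.0571 and 0.25). Nor were they with the term for genes at 0 (limma adjusted p = 0.28, 0.173, 0.298 and 0.283). Under it the log2 fold changes of Agrn (1.13 to 1.11), Adssl1 (1.12 to 1.24) and Ephx2 (-0.784 to -0.783) held, while that of Fkbp11 shrank (-1.09 to -0.514). The count was 45 without 6m replicate 4, and 2, 3 and 268 without 12m replicates 1 to 3.

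From 12m to 18m, Plac9a rose 3.42-fold, Plac9b 3.33-fold (88.2 ± 35.9 TPM, SD, n = 3, to 293 ± 40.4, SD, n = 4; limma adjusted p = 0.00339) and Inmt 7.50-fold, which was not called without 12m replicate 2 (adjusted p = 0.0904) or 18m replicate 1 (0.0586). Inmt also lost its call with the covariates (log2 fold change 2.92 to 1.87, adjusted p = 0.0673). With the term for genes at 0 its fold was larger but its error grew (3.27 ± 1.05 SE, adjusted p = 0.0635). Igsf1 fell 3.80-fold and the flavin monooxygenase gene Fmo2 5.23-fold. Limma called 2940 genes, 222 higher and 2718 lower, and after rescaling 1206 higher and 1001 lower. The count was 1388 and 1686 without 12m replicates 1 and 3, and 847 without 18m replicate 1, and within the libraries with the most genes at 0 it was 2640. It was 1165 after quantile normalization, 1427 with array weights and 848 with the term for genes at 0, and in a fit of these ages alone limma called 0, with 3729 at an unadjusted p under 0.05.

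The slope over 3m to 18m asks which genes changed gradually in adult life. Tnc fell by 0.17 on the log2 scale per month (SE 0.03, limma adjusted p = 0.00179), from 25.8 ± 5 TPM (SD, n = 5) at 3m to 3.12 ± 1.74 (SD, n = 4) at 18m, and Nrep fell by 0.14 per month. Rasgef1a fell by 0.17 per month (adjusted p = 0.0429) and was not called in 10 of the 17 fits without 1 library, with an adjusted p of 0.13 without 18m replicate 1. Neu4, a sialidase gene, rose by 0.14 per month, and Mroh7 and the myelin gene Pllp by 0.11. Limma called 1986 genes, 189 with a positive and 1797 with a negative slope, and after rescaling 828 and 1171. The count was 803, 1164, 1260 and 1229 without 18m replicates 1 to 4 and 1288 and 1218 without 3m replicates 1 and 2, and without the 3m age limma called 2, with 2663 at an unadjusted p under 0.05. With the covariates 112 slopes were called, and with the term for genes at 0 limma called none (1804 at an unadjusted p under 0.05). None of the 6 named slopes was called with either, though 5 kept at least 0.5 of their value with the covariates and 5 with the term, where the SE was larger by a median factor of 1.3 and 2.2. With the term the slope was -0.16 ± 0.05 SE for Nrep, 0.13 ± 0.07 SE for Neu4 and -0.39 ± 0.10 SE for Rasgef1a. With the covariates the slope was -0.18 ± 0.04 SE for Tnc (adjusted p = 0.0541), -0.14 for Nrep (0.0598), 0.08 for Mroh7 (0.0524), 0.12 for Neu4 (0.153), 0.07 for Pllp (0.24) and -0.05 for Rasgef1a (0.204).

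Over the 9 ages together, 9281 of 14590 genes (63.6%) differed between at least some ages by limma's F test. Tnc and Etnppl were called both from P7 to P60 and from P60 to 3m, in opposite directions.

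**Figure D4:**
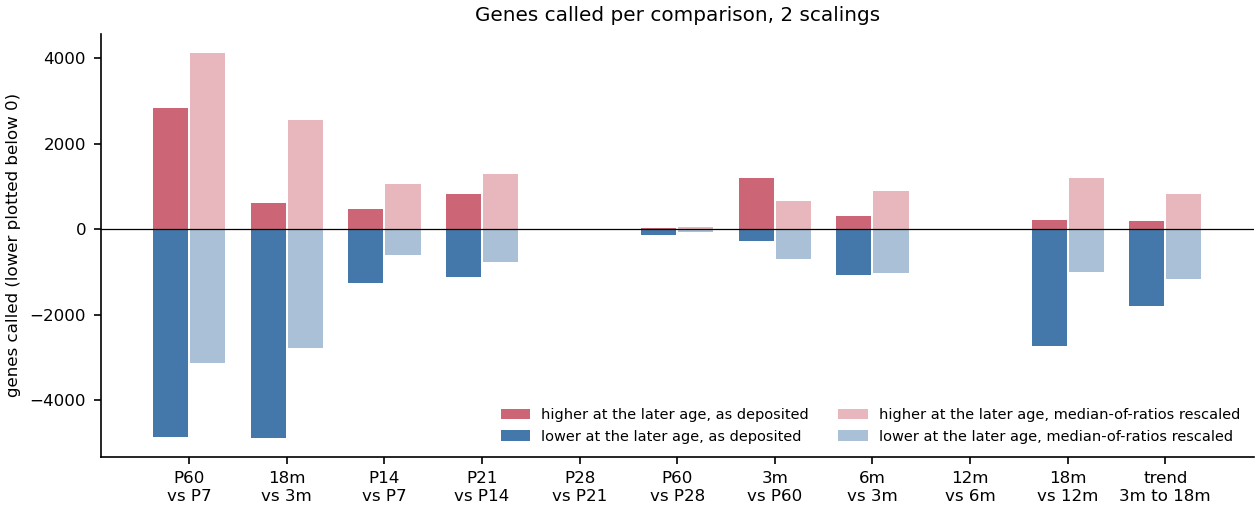
Number of genes called higher and lower by limma in each comparison (bars), for the values as deposited and after median-of-ratios rescaling. For 18m vs 3m the bars are 607 higher and 4869 lower as deposited, and 2564 and 2770 after rescaling.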

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

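The tests of the ranges of genes at 0, of scaling, of other dividing cells, of neuronal and cell cycle transcripts at 3m and of other groupings of the libraries were chosen only after the results were seen, while those of carried-over RNA, of whole neurons and of the position of the 3m libraries were fixed beforehand.

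In groups of 4 or 5 libraries, a library was singled out when its gap to the nearest other took most of the group's range (Dixon's criterion), and 27 of 400 tested groups met this, where chance picks out about 1 in 20 groups, or 20. In mean log2(TPM + 1), 18m replicate 1 was lowest for synapse-regulating astrocyte factors (4.551, others 4.843 to 4.9) and for glutamate and GABA handling (6.834, others 7.298 to 7.338), and 6m replicate 5 was lowest for ion and water homeostasis (7.392, others 7.888 to 7.969). P7 replicate 2 was highest for heat shock genes (6.853) and 3m replicate 5 lowest for immediate early genes (5.119). Among other cell types, P14 replicate 4 was lowest for neuronal genes (2.788), P14 replicate 1 highest for oligodendrocyte precursors (4.389) and 18m replicate 2 highest for border macrophages (2.089). Erythroid genes were lowest in 3m replicate 5 (8.351) and 6m replicate 2 (5.238, others 9.495 to 10.33). Among single genes, 18m replicate 1 had the highest Scgb3a1 (66.62 TPM, others up to 5.103), Ackr1 (94.23) and Ctsw (19.82, others up to 4.245). In 6m replicate 5 Ackr1 (83.8 TPM), Inmt (52.67) and Wfdc17 (9.982) were highest and Slc1a3 lowest (2316, others 3525 to 3973). In 6m replicate 1 Fabp7 (6604 TPM, others 586.4 to 899.1) and Htra3 (55.89) were highest, and in 6m replicate 3 Mobp was (175.2). P14 replicate 1 had the highest Spon2 (6.451 TPM) and Col3a1 (17.25), and P14 replicate 4 the highest Etnppl (87.87, others up to 35.03). Nrsn1 was highest in P7 replicate 2 (5.412 TPM), Ackr1 in 3m replicate 3 (28.85), and the lowest values were those of Inmt in 18m replicate 2 (19.51) and H2-Aa in 18m replicate 4 (5.526).

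Neuronal and myelin transcripts rose from P7 to P60, neuronal ones fell from 3m to 18m, and both differed between libraries of an age, the most abundant at 3m being Mbp at 661 ± 557 TPM (SD, n = 5), Snap25 at 94.5 ± 42.4 (SD, n = 5) and Camk2a at 90.7 ± 56.7 (SD, n = 5). A difference between the ranges of genes at 0 is argued against only as the whole source of the rise from P7 to P14. It stays open for P14 to P21 and for 3m to 18m, which cross ranges. Within the highest range the neuronal list mean was 2.79 to 3.23 at P14 and 2.07 to 2.35 at P7, and the oligodendrocyte mean 2.74 to 2.89 and 2.16 to 2.4 (exact permutation p = 0.0286 for each, the smallest that 70 groupings can give). Camera called both higher (adjusted p = 1.65e-06 and 0.037), though not with an estimated correlation (0.365 and 0.707), and fry called the neuronal list (0.0248) but not the oligodendrocyte list (0.646), so that the evidence is weaker for myelin. Carried-over RNA of both cell types, which magnetic isolation should remove, is a candidate source: the deviations of the neuronal and oligodendrocyte list means from their age means correlated with Pearson's r of 0.606 (permutation p = 0.0084, n = 34; Spearman's rho 0.475, permutation p = 0.033; the only such relation tested; 0.498 without the 2 farthest libraries), though with r of 0.641, 0.0667 and 0.689 in the ranges of most, middle and fewest genes at 0. Whole neurons cannot be told apart from part of their RNA, because 69.2% of 13 neuronal genes, 9 of them, followed the others with r above 0.5, between the bounds of 80 and 50% set beforehand, and Gad1, Gad2, Reln and Stmn2 did not. A change of the astrocytes or of the cortex with age stays open as untested.

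The large numbers of calls in P60 vs P7 and in 18m vs 3m, the latter mostly of lower genes, coincide with the ranges of genes at 0. Scaling is argued against as the source of the number in 18m vs 3m, since 5334 genes were called after median-of-ratios rescaling. The genes called changed in part: 3377 of the 5476 were called in both settings in the same direction, while 99.4% of the 5476 kept their sign. Whether it accounts for the share of lower genes among all calls stays open, because rescaling centres the middle gene and so by itself gives a near even split (48.1% higher). It is argued against as the whole source of that share among changes of at least 2-fold, since 21.4% of those were higher after rescaling, and 19.6 to 25.2% without any 1 library. The range of genes at 0 cannot be told apart from age: with it as a term, 39 genes were called in 18m vs 3m, where 85.8% of the earlier calls kept their sign, their median log2 fold change went from 0.57 to 0.39 and its median SE from 0.15 to 0.32, so that both a smaller change and a larger error ended calls. In P60 vs P7, 0 ages had libraries in both ranges concerned, so that no such term could be fitted. Age itself stays open.

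Cell cycle transcripts were higher at 3m (mean log2 level 3.71 ± 0.25, SD, n = 5) than at P60 (2.37 ± 0.14, SD, n = 3) and 6m (2.82 ± 0.35, SD, n = 5). A difference between ranges of genes at 0 is argued against for 3m over 6m, which share a range (exact permutation p = 0.00794, adjusted p = 0.107 over 42 tests). It stays open for 3m over P60, which lie in different ranges. The mean at 6m, in the range of 3m, was also 0.444 above that at P60 (exact permutation p = 0.0536, adjusted p = 0.126). Mislabelled libraries of P14, P21 or P28 mice are argued against by cell cycle transcripts. Mislabelled libraries of P7 mice are argued against by some other lists, which do not settle it. The test fixed beforehand did not decide this alone, as the 3m mean of 7669 other developmental genes lay at a median position of 0.45 between P60 at 0 and P7 at 1, inside its bounds of 0.4 and 0.8, but 6m lay at 0.5, so that the position does not single out 3m. Of the 5 libraries at 3m, 0 had a neuronal list mean (3.43 to 4.75) within the range of the 8 libraries of P7 and P14 (2.07 to 3.23), and 0 a cell cycle mean (3.51 to 4.12) within that of the 10 libraries of P14, P21 and P28 (2.34 to 3.17). Neuronal means also differed within 6m (2.21 to 4.03) and may hold carried-over RNA, so they cannot settle the age of a library. The cell cycle means at 3m overlapped those at P7 (3.73 to 4.07) and so do not speak against P7. Some other list means, compared only afterwards, did not overlap. Ribosomal means were 7.97 to 8.321 at 3m and 8.453 to 8.573 at P7. Those of glycolysis and glycogen were 8.416 to 8.561 and 8.115 to 8.273. Both lists argue against P7 mice, as do the neuronal means. MHC class I means overlapped (5.433 to 5.572 and 5.245 to 5.601). As 3m and P7 lie in different ranges of genes at 0, a difference between ranges could also separate these lists. Mice from outside the series were not tested. Dividing cells of another type stay open, since 4 of 7 lists of such types had a positive median at 3m against both ages. Camera called none of the 7 higher against both, but called fibroblasts higher against P60 and immature neurons higher against 6m. Division of astrocytes also stays open, as untested.

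Regrouping the libraries of a comparison, in all possible ways or in 100 drawn at random, tells how often another grouping gives as large a count. No other grouping did for P60 vs P7 (7697 genes, highest other grouping 3215; 1 of 35 groupings as large), 18m vs 3m (5476 and 3397; 1 of 100), P14 vs P7 (1728 and 1; 1 of 35), P21 vs P14 (1925 and 43; 1 of 35), 3m vs P60 (1487 and 123; 1 of 56), 6m vs 3m (1360 and 926; 1 of 100), 18m vs 12m (2940 and 2069; 1 of 35), the F test (9281 and 67; 1 of 100) and the slope (1986 and 4; 1 of 100). This argues against chance for these counts without excluding it. Each share is the smallest its groupings can give, and none was adjusted over the tests. In a fit of their ages alone, 6m vs 3m and 18m vs 12m called few or no genes. Chance stays open for the lists of P60 vs P7 (16 lists, highest other 17; 5 of 35) and of 18m vs 3m (15 and 21; 26 of 100), and for 12m vs 6m (8 genes and 1503; 24 of 56). There, the grouping of 6m replicates 1 and 4 with 12m replicate 3 called 1503 genes, which points to a structure of the samples. Its source was not tested; these 3 libraries had the lowest neuronal list means of the 8, a relation seen only afterwards. The groupings are too few for P28 vs P21 (3 and 2) and P60 vs P28 (163 and 0).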

How the results depend on the processing

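The covariates, the term for genes at 0, the fits within 1 range of genes at 0 and those without 3m were added after the data were seen; the cause of the changes was not tested. Counts stayed within 1.5 times of those reported except as follows. Without a filter P28 vs P21 called 12 genes and the slope 3328, and with a filter of 5 TPM the slope called 1041, where fewer genes were tested. After median-of-ratios rescaling P28 vs P21 called 1, 12m vs 6m 36 and the lists of 18m vs 3m 9. Quantile normalization gave 252 for P60 vs P28, 49 for 12m vs 6m, 1165 for 18m vs 12m and 1236 for the slope, and a replicate block 493 for P60 vs P28. Array weights gave 6008 for P14 vs P7, 4946 for P21 vs P14, 224 for P28 vs P21, 2480 for P60 vs P28, 3206 for 3m vs P60, 566 for 6m vs 3m, 1 for 12m vs 6m, 1427 for 18m vs 12m and 5272 for the slope. Neuronal and oligodendrocyte covariates gave 3700 for P60 vs P7, 288 for P60 vs P28 and 112 for the slope. A fold of at least 2, a stricter criterion, left 2733 genes in the F test, 1868 in P60 vs P7, 743 in 18m vs 3m, 216 in P14 vs P7, 345 in P21 vs P14, 18 in P60 vs P28, 304 in 3m vs P60, 303 in 6m vs 3m, 5 in 12m vs 6m, 128 in 18m vs 12m and 396 for the slope. A fit of only the 2 ages called 4914 in P14 vs P7, 4125 in P21 vs P14, 1 in P28 vs P21, 716 in P60 vs P28 and 7 in 6m vs 3m, and 0 by limma in 12m vs 6m (541 at an unadjusted p under 0.05) and 0 in 18m vs 12m (3729). The term for genes at 0 gave 39 for 18m vs 3m, 5 for 12m vs 6m, 848 for 18m vs 12m and 0 by limma for the slope (1804 at an unadjusted p under 0.05). Of the 5 in 12m vs 6m, 0 were among the 8 called without the term. With 6m in place of 3m, 2968 genes were called, and the slope from 6m to 18m called 2. With an estimated correlation camera called 0 lists in P60 vs P7 and 0 in 18m vs 3m, while fry called 16 (7 higher, camera 10) and 15 (2 higher, camera 12). The share of genes in opposite directions was 48.1% with a pseudocount of 0.1, 56.1% after quantile normalization, 57.8% after rescaling, 48.3% with the block and 58.4% within the highest range of genes at 0 (P14 vs P7 against 18m vs 12m), all passing Fisher's exact test; the odds ratio lay above 1 with a fold of at least 2 (66.8% in opposite directions, odds ratio 1.65, p = 0.193) and without 3m replicate 2 (46.9%, odds ratio 1.05, p = 0.665), neither passing it. Without 1 library in turn the range was 8350 to 9981 for the F test, 6173 to 6995 for P60 vs P7, 3471 to 5599 for 18m vs 3m, 628 to 1268 for P14 vs P7, 566 to 1454 for P21 vs P14, 0 to 4 for P28 vs P21, 9 to 114 for P60 vs P28, 675 to 1272 for 3m vs P60, 574 to 1559 for 6m vs 3m, 2 to 268 for 12m vs 6m, 847 to 3346 for 18m vs 12m, 803 to 2767 for the slope, 14 to 17 and 10 to 15 lists for P60 vs P7 and 18m vs 3m, and 45.5 to 50.3% for the overlap. Among named genes, 5 lost their call and 2 gained one after rescaling, 4 lost it after quantile normalization, 4 with array weights, 3 with the pseudocount and 1 with the block, which gave 2 others one, and none turned direction under these. With the covariates 22 of 60 named genes lost their call in P60 vs P7, of which Nrsn1, Mbp, Hpcal4, Kif5a, Gng13 and Nefl turned direction, 21 of 50 in 18m vs 3m and 6 of 6 slopes, and with the term for genes at 0, 48 of 50 in 18m vs 3m, where Dmp1, Gfap and Rpl6 turned direction, uncalled, while 40 of the 48 kept at least 0.5 of their fold, 26 had one at least as large and the SE grew by a median factor of 2.2. The term rests on 12m, where replicate 3 had the lowest neuronal list mean. Larger neuronal folds under it therefore do not show that those changes held. Depth is not known from TPM and could not be assessed.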

Other observations

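Haemoglobin transcripts stood out at P21. The 5 erythroid genes, among them the globin genes Hba-a1 and Hbb-bs, had a mean log2 level of 11.86 ± 0.55 (SD, n = 3) at P21, 9.25 ± 0.64 (SD, n = 4) at P14 and 9.17 ± 0.21 (SD, n = 3) at P28. All 5 rose from P14 to P21, 5 also adjusted over the list alone (camera adjusted p = 0.000493, adjusted p = 0.852 with an estimated correlation). From P21 to P28 none was called over all genes, while 5 fell adjusted over the list alone, and camera called the list lower (adjusted p = 3.25e-17, adjusted p = 0.0141 with an estimated correlation).

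The circadian clock genes moved apart in development. Of 15, 12 rose from P7 to P60 and 2 fell, as they did adjusted over the list alone (camera adjusted p = 0.000712, adjusted p = 0.407 with an estimated correlation). The 2 that fell were Arntl (2.31-fold lower) and Clock (2.01-fold lower), which encode partners in the activating arm of the clock, while Hlf, a clock output gene, was 1.82-fold higher. From 3m to 18m 5 fell and none rose, 5 also adjusted over the list alone, Hlf being 2.14-fold and Tef 1.86-fold lower (camera adjusted p = 0.862). The labels give no time of day. All 6 ependymal genes rose from P7 to P60, 6 also adjusted over the list alone, with Ccdc153 6.65-fold and Rarres2 3.53-fold higher (camera adjusted p = 0.000171, adjusted p = 0.407 with an estimated correlation), and 6 fell from 3m to 6m, 6 also adjusted over the list alone (camera adjusted p = 0.000171, adjusted p = 0.512 with an estimated correlation).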
